A study of Phoxinus septimaniae with 18 samples.

How the data were processed

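RNA from the brain, gills and liver of invasive minnows (Phoxinus septimaniae x P. dragarum) was sequenced after extraction with a column kit and TruSeq library preparation, per the labels' protocols. The fish came from a salt station near a potash mine on the Llobregat River, at 18.1 ppt, or from a reference station upstream with lower salinity. There were 3 libraries for each of the 3 tissues at each of the 2 stations, 18 in all, and the titles call them biological replicates. Each library was assigned to its group from its title and to its column from its library code. No per-sample column was left out.

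The deposited tables hold raw whole-number counts per assembled transcript, in a separate table for each tissue. Transcripts came from a de novo assembly, per the series description, and the identifiers are those of the Trinity assembler, shared by the 3 tables. Trimmomatic and DESeq2 are named in the submitters' processing notes, without versions. The aligner, the counting tool and the settings of the assembly are not given in the sources used here. Every transcript in each table reached at least 1 CPM in at least 2 of the 6 libraries of that tissue, as checked on the counts deposited. An identifier can also carry protein hits, each a short source code and a protein accession, a signal peptide tag and a count of transmembrane segments. The identifiers pair these accessions with no gene symbol, apart from a few mitochondrial entries, so accessions are given here without gene names. The 46 gene lists fixed before the data were examined are lists of symbols. None of their symbols was found among the tags (0 matches), and the lists were not tested.

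Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM factors, the quasi-likelihood fit and a two-sided F test of salt against reference. The p-values were adjusted over all features of a tissue by the Benjamini-Hochberg method, with a threshold of 0.05. Fits were made on transcripts and on counts summed per protein hit, where a transcript belongs to its first listed hit. Several hits are listed by 3838 brain, 3558 gill and 2628 liver transcripts, and hits named in the text were also summed over every transcript that lists them. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values of named hits use TMM-scaled library sizes, and other CPM values use the total count of the library. Salt effects were compared between tissues with edgeR contrasts over all 18 libraries and the transcripts present in all 3 tables; the plan had named limma on normalized values, and the count model was used because the tables hold counts. These contrasts are set across tables counted separately. A salt effect here is the difference between the salt and the reference station. Salinity and station coincide, so other differences between the stations cannot be told apart from salinity.

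The rule for named genes, written before the data were examined, needed an adjusted p under 0.05, and no feature met it in any tissue. The hits named per tissue were therefore chosen after their values were seen: the 2 with the smallest unadjusted p in each direction among hits with a mean of at least 50 counts and no overlap between the groups. Other single features were also chosen after the values were seen. Sets built from the tags in the identifiers were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, on log2 CPM with a prior count of 1.

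To compare the fish behind the libraries, the share of each transcript in the count of its assembled gene was computed for genes with at least 100 counts in all 18 libraries, centred on the tissue mean, and correlated across transcripts between libraries. Gill libraries were also compared by a chi-square per feature with at least 20 counts over both libraries. Single shares of counts carry 95% Wilson intervals, and a value of 0 is bounded by 3 counts per library. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Single values were compared by exact two-sided permutation tests; with 3 libraries against 3 the smallest p these can give is 0.1.

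The fits were tested on simulated counts with 200 features changed 4-fold or 16-fold. With the dispersions estimated from these tables, edgeR recovered 0% of the 16-fold transcripts in brain, gills and liver among 51574, 40413 and 25361 transcripts tested. It recovered 83%, 69% and 78% of the 16-fold protein hits among 14000, 13797 and 10181 hits, and 44%, 19% and 11% of the 4-fold hits. On the same simulated hits DESeq2 recovered 92%, 88% and 96% of the 16-fold and 78%, 58% and 55% of the 4-fold ones, with 92, 103 and 84 false calls against 9, 8 and 7 for edgeR. Simulated libraries were drawn independently, so the gill simulation lacks the likeness of gill reference 1 and the library labelled salt 3 described below. Its rates may not hold for the real gills. limma, without quantile normalization, robust fitting or weights, recovered 0% of the simulated 4-fold and 16-fold transcripts in all 3 tissues at the estimated dispersions. The limma variants run on the real counts called brain and liver transcripts and were not simulated, so recovery here does not say how many calls real counts give. At a dispersion of 0.05 edgeR recovered at least 99% of the transcripts of either fold.

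Alternatives were DESeq2 1.42.0, limma 3.58.1 with quantile normalization, robust fitting or array weights, other filters, size factors and thresholds, the replicate number as a block, sums per protein hit or assembled gene, and leaving out each library. The other splits of each tissue's 6 libraries into 3 and 3 were refitted, 10 splits in all per tissue, and 30 splits within tissues and 28 splits of fish codes were used for the contrasts between tissues. Each of these totals includes the stations as labelled, and so do the counts of splits that gave as many calls. The fish codes were taken as labelled, that of the gill library labelled salt 3 included. Correlations and figures were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.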

Results

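The transcriptomes of brain, gills and liver were compared between minnows from a saline river station and minnows from an upstream station. The question was how each tissue differs in fish living at high salinity. Other differences between the stations or their fish cannot be told apart from salinity. Counts covered 62498 transcripts in brain, 55872 in gills and 31568 in liver, with 22609 present in all 3 tables and 85665 distinct transcripts in total. Protein hits were attached to 59.3% of the brain transcripts, 67.6% of those in gills and 75.2% of those in liver. Total counts per library ran from 23678725 to 28731252 in brain, from 15200774 to 24222245 in gills and from 22183499 to 39881549 in liver.

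Transcript shares within genes differed between fish and were similar between tissues of the same fish code. At the level of transcripts the biological coefficient of variation was 1.13 in brain, 1.26 in gills and 1.21 in liver. It was 0.490, 0.686 and 0.630 when counts were summed per protein hit. The share of each transcript within its gene, over 10588 transcripts of 3052 genes, was correlated between brain, gill and liver libraries of the same fish code with r from 0.530 to 0.786 in 10 pairs. Libraries of different codes from different tissues gave r from -0.355 to 0.135 in 86 pairs. These correlations are across transcripts, which are not independent replicates. The gill library labelled salt 3, whose pairs are left out of both ranges, gave r = -0.0686 with the brain and -0.0817 with the liver of its own code. With the brain and liver of reference fish 1 it gave 0.636 and 0.570, and with the gill library of reference fish 1 it gave 0.669. All directions drawn from gills below depend on this label.

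**Figure D1:**
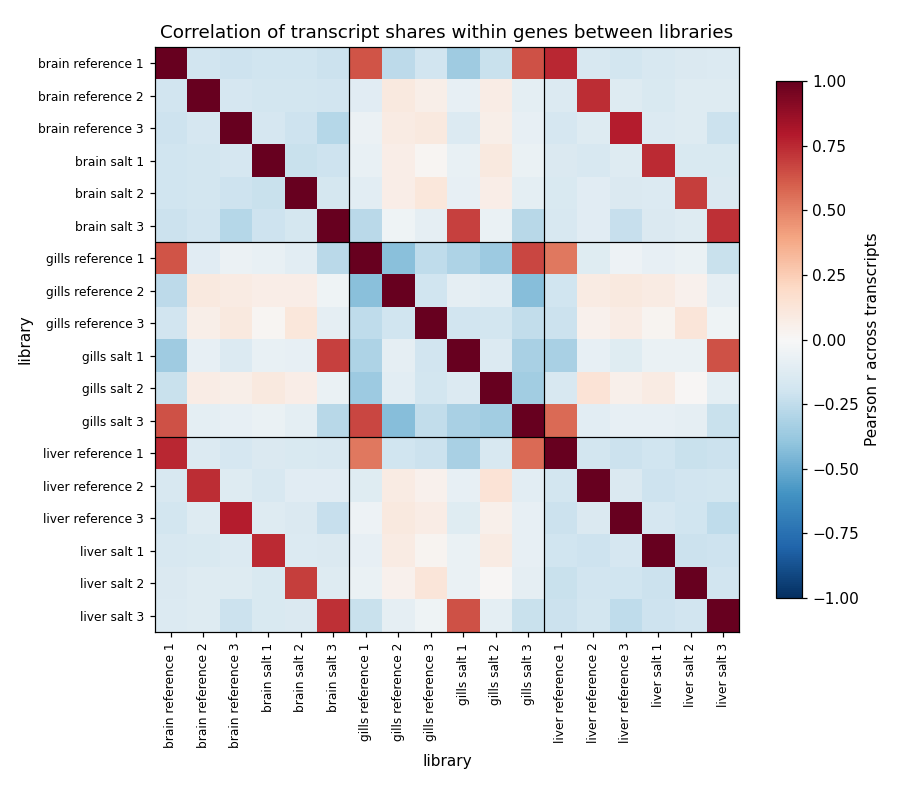
Pearson correlation across 10588 transcripts of transcript shares within genes, centred by tissue, for each pair of the 18 libraries (both axes list libraries; colour gives r). The library labelled gills salt 3 has r = 0.636 with brain reference 1 and -0.0686 with brain salt 1, the brain library of its own code.

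In brain, the protein hit ENSDARP00000116571 averaged 34.3 ± 1.66 CPM (SD, n = 3) at the salt station and 7.62 ± 0.697 CPM at the reference station over the 2 transcripts that list it first. The log2 fold change was 2.17 (SE 0.15) with an edgeR adjusted p of 0.0991. Of 2 transcripts that list this hit second, 1 averaged 60.9 ± 12.6 CPM in reference and 17.8 ± 8.52 CPM in salt brains, and the other 47.1 ± 4.11 and 55.5 ± 17.1 CPM, all on total counts. Over all 4 transcripts that list the hit, with TMM-scaled library sizes, the direction turned: 123 ± 12.7 CPM at the salt and 139 ± 2.93 CPM at the reference station, a log2 fold change of -0.17 (SE 0.11; edgeR adjusted p = 0.791). A hit to XP_005255597.1 averaged 10.3 ± 4.03 CPM in salt libraries and had 0 counts in all reference libraries, at least 63.7-fold higher against a bound of 3 counts per library. With a transcript that lists it second, it averaged 11.2 ± 5.56 CPM in salt and 3.95 ± 2.42 CPM in reference brains, a log2 fold change of 1.51 (SE 0.57). The abundant hit ENSDARP00000050378 averaged 468 ± 47.7 CPM at the salt station and 1087 ± 77.6 CPM at the reference station, a log2 fold change of -1.22 (SE 0.12; edgeR adjusted p = 0.366). ENSDARP00000079823 averaged 19.7 ± 0.158 CPM against 62.1 ± 13.1 CPM. None of these passed the edgeR threshold, and all 4 were called by DESeq2 when summed by first hit. They were chosen for a small p in the same libraries, so these calls are no separate support. In the brain simulation at the estimated dispersions DESeq2 made 92 false hit calls.

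edgeR called 0 of 57387 brain transcripts and 0 of 14202 protein hits, with 2081 transcripts (3.63%) and 901 hits at an unadjusted p under 0.05. DESeq2 called 1452 transcripts, 667 higher and 785 lower at the salt station, and 226 hits, 105 higher and 121 lower. Of these transcripts, 36.4% had 0 counts in all libraries of a station, against 3.00% of all brain transcripts. limma called 153 transcripts with quantile normalization, 112 with robust fitting and 157 with array weights. Among transcripts called by DESeq2 in genes with several transcripts, the median absolute log2 fold change was 5.31, against 0.29 for the summed count of the same genes. Without each library in turn, the counts at an unadjusted p under 0.05 ran from 2101 transcripts (without reference 3) to 3051 (without reference 2), and from 587 to 1444 hits without the same libraries. Without reference 2, edgeR called 4 brain hits.

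In gills, ENSDARP00000117017 averaged 94.4 ± 32.9 CPM (SD, n = 3) in the libraries labelled salt and 43.4 ± 6.30 CPM in reference libraries, a log2 fold change of 1.12 (SE 0.30). ENSDARP00000091035 averaged 40.8 ± 10.5 against 15.2 ± 5.96 CPM. ENSDARP00000111877 averaged 1.16 ± 0.475 CPM in salt and 8.25 ± 3.66 CPM in reference libraries, a log2 fold change of -2.83 (SE 0.65). ENSDARP00000054822 averaged 32.1 ± 5.94 against 63.5 ± 8.90 CPM. The edgeR adjusted p was 1.00 for each of the 4, and none was called by DESeq2 with all 6 libraries. Without the library labelled salt 3, DESeq2 called ENSDARP00000117017 (log2 fold change 1.32, adjusted p = 0.0103) and ENSDARP00000054822 (-1.15, 0.00770). Both hits were chosen for a small p among these libraries, so the calls are no separate support.

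**Figure D2:**
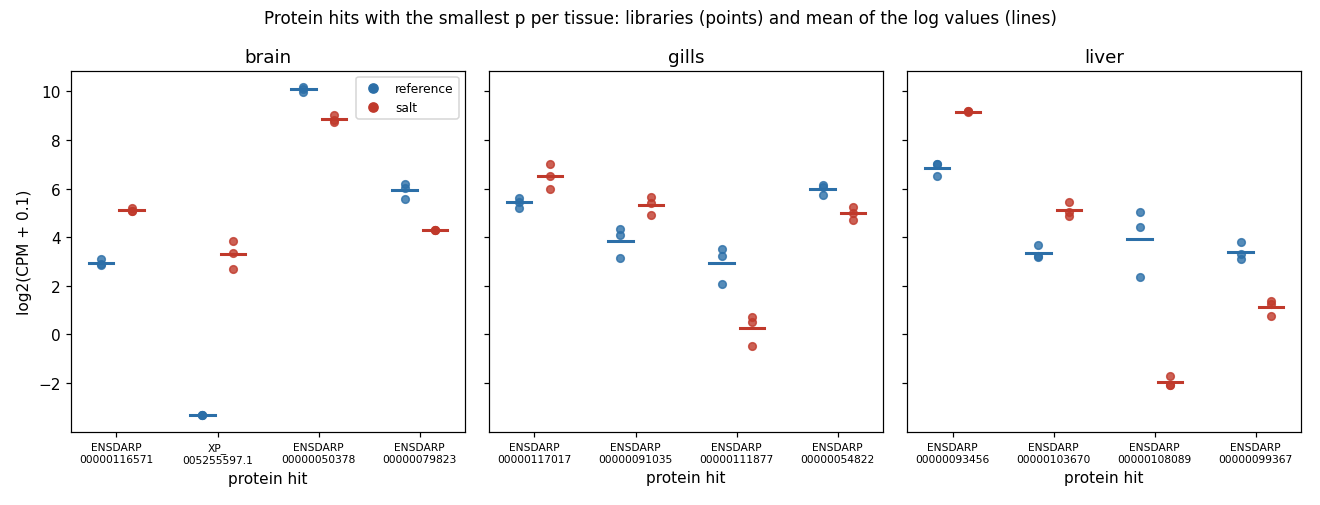
CPM of the 4 named protein hits per tissue on a log2 scale after adding 0.1 (y axis), for each library (points) and as the mean of the log values (lines), reference in blue and salt in red. Counts are summed by first listed hit. The groups do not overlap for any of these hits, which were chosen for that, and the hit to XP_005255597.1 sits at 0 counts in all reference brains.

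edgeR called 0 of 48486 gill transcripts and 0 of 14395 hits, with 377 transcripts (0.778%) and 155 hits at an unadjusted p under 0.05. DESeq2 called 260 transcripts, 157 higher and 103 lower. Of these, 76.9% had 0 counts in every library of a station, against 2.45% of all gill transcripts. DESeq2 called 4 hits by first listed hit. ENSDARP00000035665 and ENSDARP00000103388 were at 0 in all reference gills, and ENSDARP00000043854 and ENSDARP00000120217 were at 0 in all gills labelled salt; ENSDARP00000035665 stood at 53.0, 42.7 and 0.348 CPM in the libraries labelled salt 1, salt 2 and salt 3. Over all 3 transcripts that list it, ENSDARP00000120217 averaged 4.79 ± 1.55 CPM in reference gills and 4.44 ± 2.39 CPM in those labelled salt, and DESeq2 no longer called it (adjusted p = 1.00). In that fit ENSDARP00000103388, whose own count is the same, went from an adjusted p of 0.0397 to 0.0530 and was no longer called either. Without the library labelled salt 3, DESeq2 called 92 hits, 47 higher and 45 lower. In the gill simulation with all 6 libraries and the estimated dispersions it made 103 false hit calls. Simulated libraries are independent, whereas the real gills hold a matching pair, reference 1 and the library labelled salt 3, on opposite sides. The 103 is therefore no measure of false calls among the 92. Without the library labelled salt 3, edgeR called 0 transcripts, with 1783 at an unadjusted p under 0.05. Without reference 1, edgeR called 1 hit and 0 transcripts, with 2018 transcripts at an unadjusted p under 0.05. Over all 6 libraries left out in turn these counts ran from 499 (without salt 1) to 2018 transcripts, and from 55 (without salt 2) to 532 hits (without reference 1). The codes of 2 of the 3 gill reference libraries carry the letter A where all other reference libraries carry C, and the labels do not say what it marks. Without these 2, edgeR called 0 transcripts and 0 hits, with 995 transcripts and 111 hits at an unadjusted p under 0.05. The only reference left is then reference 1, which matches the library labelled salt 3 (r = 0.669), so these 0 calls say little about the letter. Without reference 1 and the library labelled salt 3 together, edgeR called 0 transcripts and 0 hits, with 2887 transcripts and 418 hits at an unadjusted p under 0.05. The fits without reference 1 leave only the 2 references coded A, so the letter and the station cannot be told apart in their counts.

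The 6 gill libraries were also split into 3 and 3 in every other way. In the 4 splits that kept reference 1 and the library labelled salt 3 on the same side, edgeR gave 1972 to 3992 transcripts at an unadjusted p under 0.05 and called 0 transcripts; it called 6 protein hits in 1 of these splits (reference 1, salt 1 and salt 3 on a side) and 0 in the others. The 6 splits that parted them, the stations among them, gave 360 to 639 transcripts at that p, with 0 transcripts and 0 hits called. DESeq2 called 170 to 1486 protein hits in the first kind of split and 4 to 9 in the second.

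**Figure D3:**
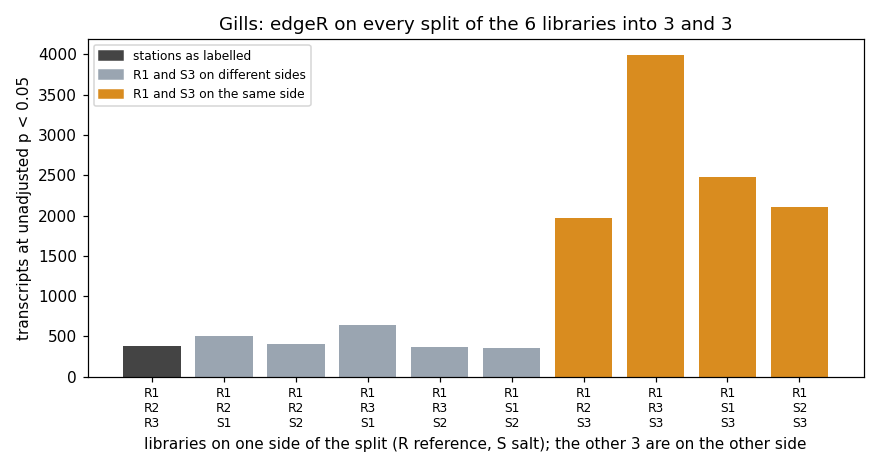
Gill transcripts at an unadjusted edgeR p under 0.05 (y axis) in each of the 10 splits of the 6 gill libraries into 3 and 3 (x axis, libraries on one side). The stations as labelled gave 377 and the highest split 3992.

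In liver, counts were concentrated in few transcripts and the degree differed between fish. The hit ENSDARP00000050237, carried by 20 transcripts, took 40.9%, 42.6% and 33.2% of all counts in salt libraries 1, 2 and 3. It took 28.9% in reference 1. The 95% Wilson intervals of these 4 shares equal the printed values except 42.5 to 42.6% in salt 2. In reference 2 and reference 3 the hit had 50 and 51 counts, 0.000151% (interval 0.000115 to 0.0002) and 0.000164% (0.000125 to 0.000216) of the total. The means were 38.9 ± 5.0% and 9.64 ± 16.7% (SD, n = 3; exact permutation p = 0.1, the smallest possible). The 10 most abundant transcripts took 54.2 ± 6.68% of counts in salt and 34.1 ± 7.72% in reference livers (n = 3; exact permutation p = 0.1). The labels give no sex or reproductive state for the fish.

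**Figure D4:**
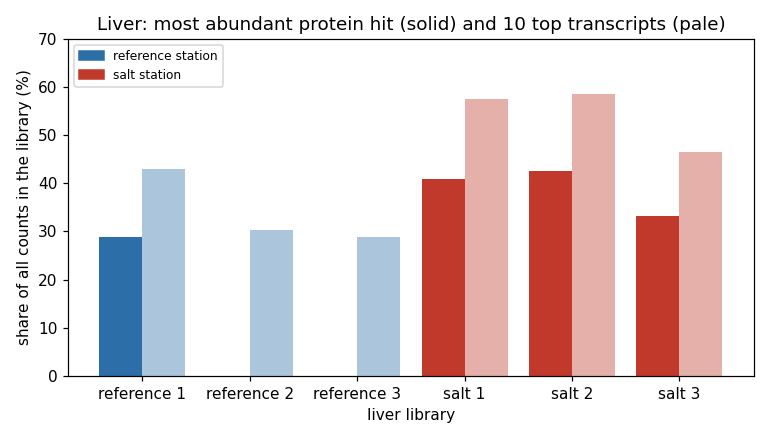
Share of all counts in each liver library (y axis, %) taken by the hit ENSDARP00000050237 (solid bars) and by the 10 most abundant transcripts of that library (pale bars). The hit reached 28.9% in reference 1 and 33.2% to 42.6% in the salt libraries, and 50 and 51 counts in the other reference libraries.

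Among other liver hits, ENSDARP00000093456 averaged 577 ± 13.5 CPM (SD, n = 3) at the salt station and 117 ± 21.2 CPM at the reference station, a log2 fold change of 2.30 (SE 0.32; edgeR adjusted p = 0.676). ENSDARP00000103670 averaged 35.3 ± 7.04 against 10.3 ± 2.00 CPM. ENSDARP00000108089 averaged 0.158 ± 0.0375 CPM in salt livers, from 10 counts in all, and 19.6 ± 13.8 CPM in reference livers. ENSDARP00000099367 averaged 2.12 ± 0.456 against 10.7 ± 2.91 CPM, a log2 fold change of -2.32 (SE 0.34; edgeR adjusted p = 0.676). All 4 were called by DESeq2 and none by edgeR with all 6 libraries. Without reference 2, edgeR called ENSDARP00000108089 (adjusted p = 0.0394). The 4 hits were chosen for a small p among these libraries, so these calls are no separate support. In the liver simulation at the estimated dispersions DESeq2 made 84 false hit calls.

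edgeR called 0 of 28679 liver transcripts and 0 of 10406 hits, with 985 transcripts (3.43%) and 691 hits at an unadjusted p under 0.05. DESeq2 called 739 transcripts, 311 higher and 428 lower, and 190 hits, 97 higher and 93 lower. Of these transcripts, 46.4% had 0 counts in all libraries of a station, against 3.86% of all liver transcripts. limma called 3 transcripts with quantile normalization, 6 with robust fitting and 7 with array weights. edgeR called 9 hits without reference 1 and 1 hit, ENSDARP00000108089, without reference 2. Without each library in turn, the counts at an unadjusted p under 0.05 ran from 1167 to 1823 transcripts and from 466 to 1090 hits, lowest without salt 3 and highest without reference 1. Without reference 1, the reference livers left are those with 50 and 51 counts of ENSDARP00000050237. Station then coincides with a large share of that hit, so the 9 calls and highest counts cannot be told apart from traits of fish that go with it.

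Classes of proteins were read from the tags of the identifiers. Of 8 sets, covering signal peptides, numbers of transmembrane segments, hits with the DANRE code and transcripts without a hit, limma's camera called 0 in brain, gills and liver. The smallest camera adjusted p was 0.532, for 404 brain transcripts with 7 transmembrane segments, which had a median log2 fold change of 0.12. In liver, 1257 transcripts with 2 to 6 segments had a median of -0.15, against -0.12 for all liver transcripts. camera, which sets a class against the other transcripts, gave an adjusted p of 0.983 at the preset correlation and 0.951 at the estimated one. fry, which sets a class against no change, gave 0.00947. These sets were chosen after the identifiers were seen.

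The differences between stations were compared across tissues. Fold changes were correlated across 22456 transcripts between brain and liver with r = 0.55, and across 9437 hits with r = 0.22. The brains and livers came from the same 6 fish codes, and the 9 other splits of these fish gave r from 0.573 to 0.609 for transcripts and from 0.199 to 0.295 for hits. Between brain and gills r was 0.10 over 32309 transcripts, and between gills and liver 0.05 over 22327; across hits r was 0.07 over 11819 and -0.02 over 9628. Some fish codes are shared here too, and for transcripts the 27 other splits that kept the libraries of a code together gave different values by the place of gill reference 1 and the library labelled salt 3. In the 17 that parted them, as the stations do, r ran from 0.0561 to 0.106 and from 0.0278 to 0.121, and in the 10 that kept them on the same side from 0.201 to 0.258 and from 0.125 to 0.239. Transcripts are not independent replicates. Among transcripts called by DESeq2, 55 were higher in both brain and liver where independent lists would share 2.24, and 80 were lower in both against 4.06. Together these are 135, and 2 other splits of the same fish, drawn at random, shared 113 against 2.59 and 167 against 4.76. Of hits, 5 were higher in both against 0.644 and 11 lower against 0.662, 16 in all against 1.31; the 9 other splits, with shorter lists, shared 3 to 10 against 0.0443 to 0.427. Brain and gills shared 1 transcript called higher, against 1.09.

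A direct test of the difference in salt effect between tissues, with edgeR over 22609 transcripts, called 5 transcripts between gills and brain, 4 between liver and brain and 6 between liver and gills. These were 8 distinct transcripts, and all 8 had 0 counts in every library of a group. Of 30 splits within each tissue, the stations as labelled counted among them, 15, 25 and 19 gave at least as many calls. The drawn splits part tissues of the same fish. Of 28 splits that kept the libraries of a fish code together, the stations again counted, 15, 24 and 18 did. Without each of the 18 libraries in turn the 3 counts ran from 5 to 40, from 3 to 32 and from 4 to 44, highest without gill reference 1, liver reference 1 and gill reference 1. Without gill reference 1, all reference gills left are coded A. Without liver reference 1, station coincides in liver with a large share of the most abundant hit. The edgeR contrasts do not model that tissues share fish; limma with fish as a block called 3, 11 and 14. Summed per hit, ENSDARP00000067907 averaged 22.1 ± 4.76 CPM in reference and 13.3 ± 1.85 CPM in salt brains, and 5.90 ± 1.38 and 9.96 ± 1.25 CPM in reference and salt livers (n = 3). The difference between its salt effects in liver and brain was 2.28 on the log2 scale, at an edgeR adjusted p of 0.0163. In this contrast limma called 1 hit with the block and 1 without it. Hits called by limma were counted and not listed, so they need not be the hit called by edgeR. The contrasts per hit were not refitted on other splits. The CPM above use total counts, whereas the contrast uses TMM factors. Without scaling factors the difference was 1.49 (SE 0.36; adjusted p = 0.0550) and not called, while 98 hits were called in liver minus brain and 307 in liver minus gills, against 1 and 1 with TMM. Without the 10 most abundant liver genes the difference was 2.28 with TMM (adjusted p = 0.0160) and 2.28 without factors (0.0417). ENSDARP00000007836 was called in gills against brain (edgeR adjusted p = 0.0336) and in liver against gills (0.0189); the single transcript that lists it first had 0 counts in all reference gills and 1.72 ± 0.546 CPM in gills labelled salt. Without the block limma called 0 hits in both contrasts, and with it 1 and 0. Over all 5 transcripts that list this hit, the means were 53.1 ± 4.55 CPM in reference gills and 46.3 ± 8.15 CPM in those labelled salt, and edgeR called it in neither contrast (adjusted p = 1.00 and 0.992).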

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

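The tests of a shared fish, of a mixture, of a repeated deposit and of station alone were chosen after the results they measure had been seen. The splits for the contrasts between tissues were set once the real counts were known, and the base rate of the gene sums was added after their test; the others were set before. The salt effect, here the difference between the stations, was compared between tissues by a direct edgeR test. The test called 5 transcripts in gills minus brain, 4 in liver minus brain and 6 in liver minus gills. Splits within each tissue gave as many calls in 15, 25 and 19 of 30, with up to 21, 38 and 23 in another split, but the drawn ones part tissues of the same fish. Counts of splits with as many calls, here and below, include the stations as labelled. In 28 splits that kept the libraries of a fish code on the same side, 15 gave as many in gills minus brain (highest other 24) and 18 in liver minus gills (highest other 34), so chance was not excluded there; for liver minus brain (24 of 28, highest other 18) these hold only 10 groupings, too few to test chance at 0.05. Splits with several times the real count point to a structure of the samples, and the larger counts of limma with fish as a block (11 in liver minus brain, 14 in liver minus gills) were not tested by splits. Single libraries also moved these counts, to as many as 40, 32 and 44 without gill reference 1, liver reference 1 and gill reference 1. In those fits station coincides with the code letter A in gills, or with a large share of the most abundant hit in liver.

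DESeq2 called 1452 transcripts in brain, 260 in gills and 739 in liver where edgeR called 0. Among transcripts tested in both brain and liver, the stations gave 231 higher and 291 lower in brain. In liver they gave 221 higher and 318 lower. The 2 other splits of the same fish, drawn at random after the results were seen, gave 337 and 450 in brain. In liver these splits gave 343 and 489, and 2 splits are too few to test chance. If variants carried by single fish made the calls between stations, the summed count of the gene would rarely move. A difference between stations in transcript use inside genes would leave it unmoved as well, so a low share cannot tell these apart. Each called transcript is also part of its own gene sum. Of the called transcripts in genes with several transcripts, 22.4% in brain, 2.92% in gills and 23.2% in liver had a gene sum at an unadjusted edgeR p under 0.05 in the same direction. Single-fish variants and a difference between stations cannot be told apart in any tissue: brain and liver lie between the bounds of 20% and 50%, and in gills only 1.05% of all gene sums reached that p in either direction (6.41% in brain, 6.39% in liver), so a low share was nearly fixed. With 10 splits of 6 libraries chance cannot be tested at 0.05: as many transcripts at an unadjusted p under 0.05 came from 1, 8 and 2 of the 10 in brain (2081, highest other 1990), gills (377, highest other 3992) and liver (985, highest other 1079), and as many DESeq2 hits from 1, 10 and 1 (226, 4 and 190, highest other 221, 1486 and 180).

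The gill library labelled salt 3 shared its transcript variants with reference fish 1, and the 4 gill splits that kept both libraries on the same side gave 1972 to 3992 transcripts at an unadjusted p under 0.05 against 377 for the stations, which points to a structure of the samples. The correlation of the library labelled salt 3 with its own code was at most -0.0686, inside the range of -0.355 to 0.135 for unrelated libraries. This argues against a mixture with a large share of RNA from the fish of that code. A small share, or a mixture of reference fish 1 with another fish, was not tested. Repeated deposit of a single library is argued against by a median chi-square per gene of 1.81 against reference 1, where parts of a single library drawn at random gave 0.467 per transcript and other gill pairs give 9.43 to 25.5. A mislabelled sample, with the library labelled salt 3 made from reference fish 1, may explain the pattern: its lower correlation with the brain and liver of that fish was 0.570, in the range of pairs from the same fish. Reference 1 itself matched its own brain at 0.630, so no partner of a swap was found, and a close relative of that fish was not tested.

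In liver, a single protein hit took a large share of counts in 4 of 6 libraries. Its abundance, with that of other top genes, may set the scaling between stations, since the ratio of mean TMM factors, salt over reference, was 0.550 with all features and 0.954 without the 10 most abundant genes. Station alone cannot be told apart from traits of single fish, because the 28.9% in reference 1 comes from a single library. Sex and reproductive state, which the labels do not give, stay open and were not tested.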

How the results depend on the processing

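Chosen after seeing the data were sums per assembled gene, the non-legacy edgeR fit, DESeq2 on hit or gene sums, DESeq2 for shared calls, gills without reference 1 and salt 3 together, DESeq2 without salt 3, liver without the 10 most abundant genes, the count minimums and single-library fits behind the shares, sums over all listed hits, other splits of the fish, and all alternatives for the contrasts between tissues except the fish block. The edgeR count of called transcripts was also 0 in all 3 tissues without a filter, with the stricter filter, with DESeq2 size factors, at the other thresholds, with the non-legacy edgeR fit, per protein hit or assembled gene and, for transcripts, without each library in turn. In simulations at the estimated dispersions, the edgeR fit used in the report recovered 0% of 16-fold changes in transcripts. Its count of 0 transcripts therefore does not exclude changes. Per protein hit it recovered 83%, 69% and 78% of 16-fold changes in brain, gills and liver, and 44%, 19% and 11% of 4-fold ones. The other edgeR settings were not simulated. The simulated gills lack the likeness of reference 1 and the library labelled salt 3, so the gill rates may not hold for the real gills. In brain the count was 153 with limma after quantile normalization, 112 with robust limma, 157 with array weights, 1452 with DESeq2, and 226 and 404 with DESeq2 on hit and gene sums. In gills DESeq2 gave 260, 4 and 5 on transcripts, hits and genes, and 92 hits without the library labelled salt 3. In liver the 3 limma fits gave 3, 6 and 7, and DESeq2 gave 739, 190 and 264. At an adjusted p under 0.1 edgeR called 1 brain hit. Without each library, called hits ranged from 0 to 4 in brain (4 without reference 2), 0 to 1 in gills (1 without reference 1) and 0 to 9 in liver (9 without reference 1, 1 without reference 2). In liver without reference 1, station coincides with a large share of the hit ENSDARP00000050237. In gills without reference 1, all references left are coded A. Transcripts called the same way by DESeq2 numbered 135 in brain and liver and 1 in brain and gills. For the DESeq2 transcript calls, variants of single fish were tested through gene sums and left undecided; no cause was tested for the other differences between tools. For the contrast between gills and brain, limma gave 2 and limma with fish as a block 3; with that block liver minus brain gave 11 and liver minus gills 14. Without each library these counts ran from 5 to 40 (highest without gill reference 1), from 3 to 32 (highest without liver reference 1) and from 4 to 44 (highest without gill reference 1). Numbers in the titles did not pair the fish: deviations of same-numbered libraries correlated across transcripts from -0.0279 to -0.0113 in brain, -0.268 to 0.172 in gills and 0.00858 to 0.0177 in liver. With this number as a replicate block edgeR called 0 transcripts in each tissue, with 1183, 192 and 546 at an unadjusted p under 0.05. Of 208 alternative fold changes of the 12 named hits, 11 passed the threshold. They were all 4 brain and 4 liver hits with DESeq2, 2 gill hits with DESeq2 without salt 3, and 1 liver hit with edgeR without reference 2. The named hits were chosen for a small p among these libraries, so these calls are no separate support. Direction turned for 1 value: summed over all transcripts that list it, the brain hit ENSDARP00000116571 stood at -0.17. Without the 2 gill reference libraries coded A, 1 reference remains and is assumed to vary like the salt libraries; edgeR called 0 transcripts and 0 hits, which says little because that reference matches the library labelled salt 3. Without reference 1 and salt 3 together it also called 0 of both. Pseudocounts for normalized values and the alternatives for the symbol lists were not run, as the tables hold counts and no symbol matched.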

Other observations

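Library codes name 9 fish, 4 from the salt and 5 from the reference station, against 6 in the series description, and 3 codes have all 3 tissues. Fish reference 2 stood apart in single mitochondrial transcripts. Other transcripts of the same genes were not summed, so the values below do not give the expression of a whole gene. A transcript with a COX1 hit, a subunit of the mitochondrial respiratory chain, reached 22750 CPM in its brain and 7452 CPM in its liver, against 133 to 195 CPM and 27.1 to 56.5 CPM in the other brains and livers. A transcript with the mitochondrial hit YP_203382.1 showed the opposite: 0.453 CPM in its brain and 0.0303 CPM in its liver, from 11 counts and 1 count, against 4610 to 6207 CPM and 718 to 1170 CPM in the others.

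Gill libraries also differed in transcripts whose hits carry source codes that are rare in the tables. The 148 gill transcripts coded TETTH or PARTE summed to 526, 239 and 0.0414 CPM in reference 1, 2 and 3, and to 96.0, 5.70 and 450 CPM in the libraries labelled salt 1, 2 and 3. The 83 transcripts coded HYPDU, DROME, CAEEL or CAPOW summed to 23.8, 351 and 28.2 CPM in the reference gills and to 780, 166 and 25.1 CPM in those labelled salt.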
